A study of Manihot esculenta with 11 samples.

How the data were processed

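Total RNA from cassava roots was labelled with Cy3 and hybridised to a custom Agilent array, as described in the labels. The samples were grouped by the stage in their titles. There were 3 fibrous roots, 3 developing storage roots, 3 mature storage roots and 2 technical repeats from stored slices. The scanner files give spot intensity: per the file headers, the authors extracted it with Agilent Feature Extraction version 9.5.3.1, whose processed signal is background-subtracted and spatially detrended, with surrogate values in place of signals too low to measure. The series table deposited by the authors holds log2 values. Each of its columns matched the quantile-normalized log2 processed signal of its array (r of at least 0.9998 across probes), with a median of 8.24 in every column. It is thus neither centred per probe nor a ratio. Its values served only as an alternative.

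The arrays hold 43097 spots, of which 41680 are no controls and measure 20840 probes, each on 2 spots. No probe has a gene description in the files, and none of the probes' source names is a transcript accession of the reference table, which lists 34312 genes of the organism. Genes are therefore not named, and the sequences were not placed on a genome. The 44 gene lists fixed before the data were examined could not be tested, nor could their alternatives. The rule for named genes fixed at the same time required an annotation and so named none. In its place, up to 2 rising and 2 falling probes per comparison are given, chosen by the rest of that rule: the largest changes among probes with an adjusted p under 0.05, no overlap between the groups' arrays, and a signal well above background and unsaturated on all arrays of both groups. The same selection was used for the stored slices after the data were seen. The limit of 2 was also set then.

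The log2 processed signal of each spot was scaled by subtracting the array's 75th percentile over non-control spots. Spots flagged as outliers were left out, and the 2 spots of a probe were averaged. Probes were tested if well above background (both spots) on all arrays of at least 1 group, which left 16720 for the stages and 17283 with the stored slices. limma 3.58.1 in R 4.3.3 fitted the group means, with the empirical Bayes variance, 6 residual degrees of freedom and Benjamini-Hochberg adjustment over the probes of each comparison, and probes with an adjusted p under 0.05 were called. The 3 stage comparisons shared an estimate of the spread. The stored-slice repeats were averaged to 1 sample in a second fit that also held the 9 stage samples. The labels state that the stage samples came from 3 independent plants, but not which samples share a plant. A 1-colour signal near the background understates changes, because background binding and surrogate values set a floor.

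Alternatives fixed before the data were examined were normexp background correction (offset 50), quantile normalization, the authors' table, no filter or a filter on all arrays, slide as a fixed or random block or within slides, the replicate number as a block, a variance trend with robust estimation, leaving out each array, a 2-fold minimum, an adjusted p under 0.01, the 2 groups alone, and each technical repeat alone. Leaving out the probes of reverse clone-end reads was added later. Slides were told apart by their barcodes, each with a single scan.

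Whether equal replicate numbers pair the samples was checked on the deviations from the group means. Same-numbered fibrous and mature arrays correlated at 0.43, 0.37 and 0.33 across probes, and same-numbered developing and mature arrays at 0.19, 0.29 and 0.19. These all exceed the limit of 0.1 that was set for pairing, so the numbers were read as pairing the samples of those comparisons from the data, not from the labels. The replicate block gave 4547 and 0 calls in those comparisons, against 3555 and 0 without it. Fibrous and developing arrays of equal number correlated at 0.28, -0.13 and 0.27 and were not read as paired. This reading contradicts itself, since equal numbers that mark a plant in those comparisons would mark it here too. In the comparisons read as paired, each same-numbered pair correlated more closely than any unlike-numbered one. The unlike pairs reached at most 0.04 for fibrous with mature arrays and 0.11 for developing with mature arrays. Unlike-numbered arrays still passed the limit in places, such as fibrous root 3 with developing storage root 2 (0.42) and developing storage root 2 with mature storage root 3 (0.11). The limit therefore does not identify plants, and the main counts come from fits without pairing.

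The fits were tested on simulated data with the real probes' means and spreads, over 16720 probes with 200 of them changed. Each probe had the same simulated spread in all groups. For developing against fibrous root, none of the 2-fold, 59% of the 4-fold and 91.5% of the 8-fold changes were recovered. For mature against fibrous root the shares were 0, 61 and 93.5%. For the stored slices none of the 4-fold and 69% of the 8-fold changes were recovered. Shared fibrous arrays were simulated 20 times with unchanged groups. Overlaps of at least 30 bases between probes were found in both orientations with Python 3.11.15. Control probes were left out of all tests. The p-values measure the spread between these samples only.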

Results

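Root RNA of cassava (Manihot esculenta), a tropical crop grown for its starchy storage roots, was hybridised to 11 arrays. The 9 stage samples came from plants of cultivar TMS60444, a line often used for transformation, that had grown in a field to an age of 4 months. They were fibrous roots (the thin absorbing roots), developing storage roots and mature storage roots, with 3 samples of each stage from independent plants. The other 2 arrays held RNA from slices of storage root of this cultivar that had been stored, which the study used as technical repeats and whose age the labels do not give. Each array measured 20840 probes of 60 bases in a single dye, each probe on 2 spots. The array's files describe no probe by a gene, so probes are given by their ID and sequence, and their genes and genome positions are not given here. The design asks which transcripts differ between the 3 stages of root development, and how closely the repeats agree.

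Between 15609 and 17599 probes were well above background on an array. The 75th percentile of the signal lay between 1779 and 4411 scanner units. It averaged 3983 ± 420 (SD, n = 3) in fibrous roots, 2748 ± 919 (SD, n = 3) in developing storage roots and 2369 ± 615 (SD, n = 3) in mature storage roots. The smallest exact two-sided permutation p among these group differences was 0.1, which is also the smallest that 3 arrays against 3 can give. For the number of probes well above background the exact two-sided permutation p was 0.2 or higher in each comparison. The number of arrays limits the precision of every value below. All 3 fibrous arrays lay on slide 1, together with developing storage root 1. Slide 2 held developing storage roots 2 and 3 and mature storage roots 1 and 2, and slide 3 held mature storage root 3 and both stored-slice arrays.

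The first principal component of the stage arrays took 53.9% of the variance over the 14401 probes detected on all 9 arrays, and it parted the fibrous from the storage roots. It also parted the slides, with negative scores for all arrays of slide 1 and positive scores for those of slides 2 and 3. Fibrous roots scored from -97.1 to -57.1 on it, and the mature roots from 40.9 to 62.3. Developing storage roots 2 and 3 scored 39.8 and 72.2, close to the mature roots or beyond them, and developing storage root 1 scored -26.1. That array stood apart from its own group. Its correlation with developing storage roots 2 and 3 across 14072 probes was 0.922 and 0.880, against 0.982 between those arrays. Its correlations with fibrous arrays were 0.923 to 0.932 and with mature arrays 0.930 to 0.936. Within the fibrous group r ranged from 0.975 to 0.982, and within the mature group from 0.972 to 0.974. These correlations run across probes, which are not independent replicates.

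**Figure D1:**
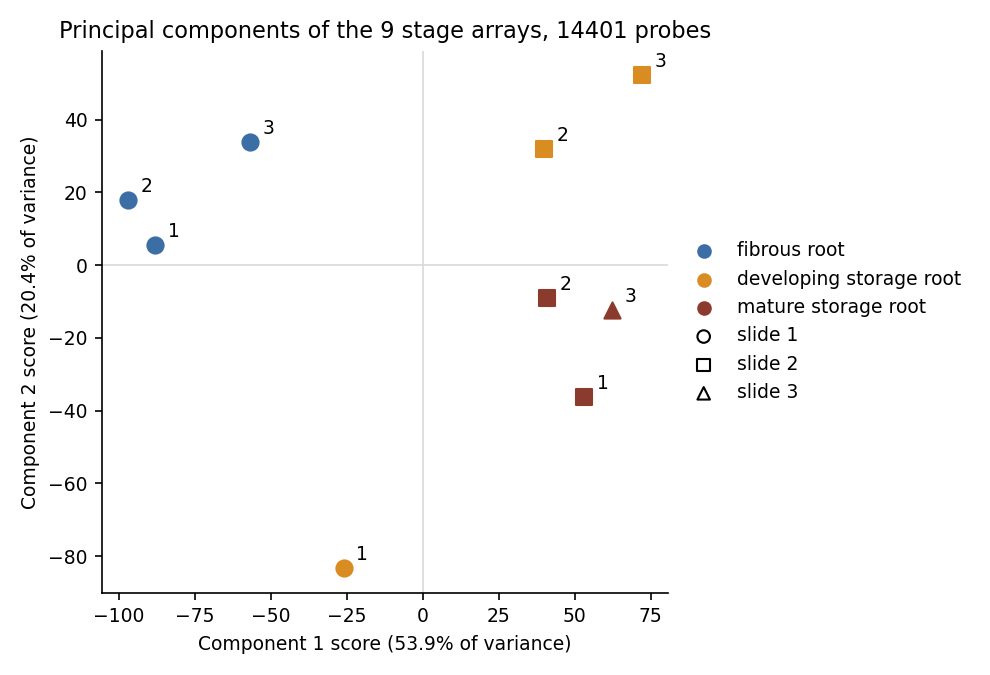
Scores of the 9 stage arrays on the first 2 principal components of log2 signal over 14401 probes. Colours give the stage, symbols the slide and digits the replicate, and developing storage root 1 lies apart at a second-component score of -83.3.

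Developing storage roots differed from fibrous roots at 1938 of 16720 probes (limma, Benjamini-Hochberg adjusted p under 0.05). Of these, 1288 were higher and 650 lower in developing storage root. The median change was 1.74 log2 units among the higher probes and -2.65 among the lower ones, so the falls were fewer and larger. Quantile normalization gave 1011 higher and 778 lower probes, or 56.5% higher in place of 66.5%. Changes of 8-fold or more were found for 131 higher and 258 lower probes. Among the 1523 called probes that passed the selection for naming, the steepest fall was that of CUST_15561_PI390660497 (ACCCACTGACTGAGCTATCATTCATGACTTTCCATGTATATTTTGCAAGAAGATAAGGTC). Its log2 signal relative to the array's 75th percentile was 3.79 ± 0.55 (SD, n = 3) in fibrous root and -3.72 ± 0.43 (SD, n = 3) in developing storage root, a fall of 182-fold (log2 change -7.51, SE 0.43, limma adjusted p = 4.9e-05). The probe CUST_13664_PI390660497 (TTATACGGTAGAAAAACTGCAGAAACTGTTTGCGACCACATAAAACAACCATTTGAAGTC) fell 148-fold (log2 change -7.21, SE 1.11, limma adjusted p = 0.0045), from 1.80 ± 2.51 (SD, n = 3) in fibrous root to -5.41 ± 0.67 (SD, n = 3). Among the rises, CUST_3309_PI390660497 (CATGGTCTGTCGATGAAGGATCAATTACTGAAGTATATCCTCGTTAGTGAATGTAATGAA) was 92.1-fold higher in developing storage root (log2 change 6.52, SE 1.24, limma adjusted p = 0.011). Its spread in developing storage root was wide (0.49 ± 3.09, SD, n = 3), from 4.04 in developing storage root 1 to -1.56 in developing storage root 3. Its log2 change was 4.75 without developing storage root 1 and 10.08 with slide as a fixed block. Without fibrous root 2 its limma adjusted p was 0.051 (log2 change 6.28), and over its 21 alternatives this p ranged from 0.00062 to 0.051. The probe CUST_9814_PI390660497 (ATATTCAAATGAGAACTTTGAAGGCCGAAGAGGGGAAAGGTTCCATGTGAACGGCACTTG) was 83.9-fold higher (log2 change 6.39, SE 1.04, limma adjusted p = 0.0058) and lost its call with slide as a fixed block (log2 change 5.86, adjusted p = 0.075, with a range of 0.0035 to 0.075 over its 21 alternatives).

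The count for developing against fibrous root moved with single arrays. It was 856 without fibrous root 1, 783 without fibrous root 2, 971 without developing storage root 2 and 1110 without developing storage root 3. Without developing storage root 1 it rose to 5246, of which 3639 were higher. With slide as a fixed block 604 probes were higher and 583 lower, and 646 of these 1187 were also called without the block. Within slide 1, which holds the fibrous arrays and developing storage root 1 only, 1295 probes differed, 616 higher and 679 lower, and 661 of them were also called with all arrays. That lone array was assumed to vary like the fibrous ones, and it is the one apart from its own group, so this value cannot stand for the stage. The fixed-block changes of this comparison, that of CUST_9814_PI390660497 included, rest on the same arrays of slide 1 by construction. They are no separate check, and a call lost under that block does not show a slide effect.

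Mature storage roots differed from fibrous roots at 3555 of 16720 probes by the same test. Of these, 2274 were higher and 1281 lower in mature storage root, with median changes of 1.49 and -2.28 log2 units. The falls again included more large changes, with 431 probes at least 8-fold lower and 160 at least 8-fold higher. There were 334 probes well above background on all fibrous arrays and on no mature array, and 63 probes with the opposite pattern. Detection is read before scaling, and the 75th percentile averaged 3983 on fibrous against 2369 on mature arrays. This imbalance may therefore hold a difference in array brightness. Among the 2913 called probes that passed the selection for naming, CUST_3309_PI390660497 rose most, from -6.03 ± 0.53 (SD, n = 3) in fibrous root to 4.40 ± 0.89 (SD, n = 3) in mature storage root, which is 1380-fold (log2 change 10.43, SE 1.24, limma adjusted p = 0.00081). With slide as a fixed block its log2 change was 15.80 and with slide as a random block 12.49, so the size is not settled. The probe CUST_9814_PI390660497 was 87.1-fold higher (log2 change 6.44, SE 1.04, limma adjusted p = 0.0035), and lost its call with slide as a fixed block (log2 change 5.69, adjusted p = 0.16, with a range of 0.0017 to 0.16 over its 20 alternatives). The probe CUST_15561_PI390660497 fell 304-fold (log2 change -8.25, SE 0.43, limma adjusted p = 2.2e-05). The probe CUST_7173_PI390660497 (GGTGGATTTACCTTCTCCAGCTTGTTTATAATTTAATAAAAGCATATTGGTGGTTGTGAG) fell 500-fold (log2 change -8.97, SE 1.89, limma adjusted p = 0.012), from 5.46 ± 0.64 (SD, n = 3) to -3.50 ± 0.77 (SD, n = 3). Developing storage root 1 stood at the fibrous level for this probe, 5.88, and developing storage roots 2 and 3 at -0.66 and -3.71. With slide as a fixed block the change of CUST_7173_PI390660497 was -0.63 (adjusted p = 0.85) and with slide as a random block -5.83 (adjusted p = 0.12). Over its 20 alternatives this p ranged from 4.5e-05 to 0.85.

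No slide held both fibrous and mature roots, so no value within a slide exists for this comparison. With slide as a fixed block 615 probes were higher and 744 lower in mature storage root, and 657 of these 1359 were also called without the block. With slide as a random block 640 were higher and 722 lower, so the excess of higher probes turned under both. The fixed-block fit joins fibrous to mature roots only through developing storage root 1 on slide 1 and developing storage roots 2 and 3 on slide 2. The count was 1691 without fibrous root 1, 1478 without fibrous root 2, 1846 without mature storage root 1, 1777 without mature storage root 3 and 5956 without developing storage root 1. The split of the calls also moved with the scaling. Quantile normalization gave 1720 higher and 1476 lower probes, or 53.8% higher in place of 64.0%. The median change over all tested probes was 0.34 log2 units in this comparison and 0.28 in developing against fibrous root with the 75th percentile scaling, and 0.13 and 0.07 with quantile normalization. Directions are therefore relative to the scaling of each array, and a small change near these medians has no settled sign.

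**Figure D2:**
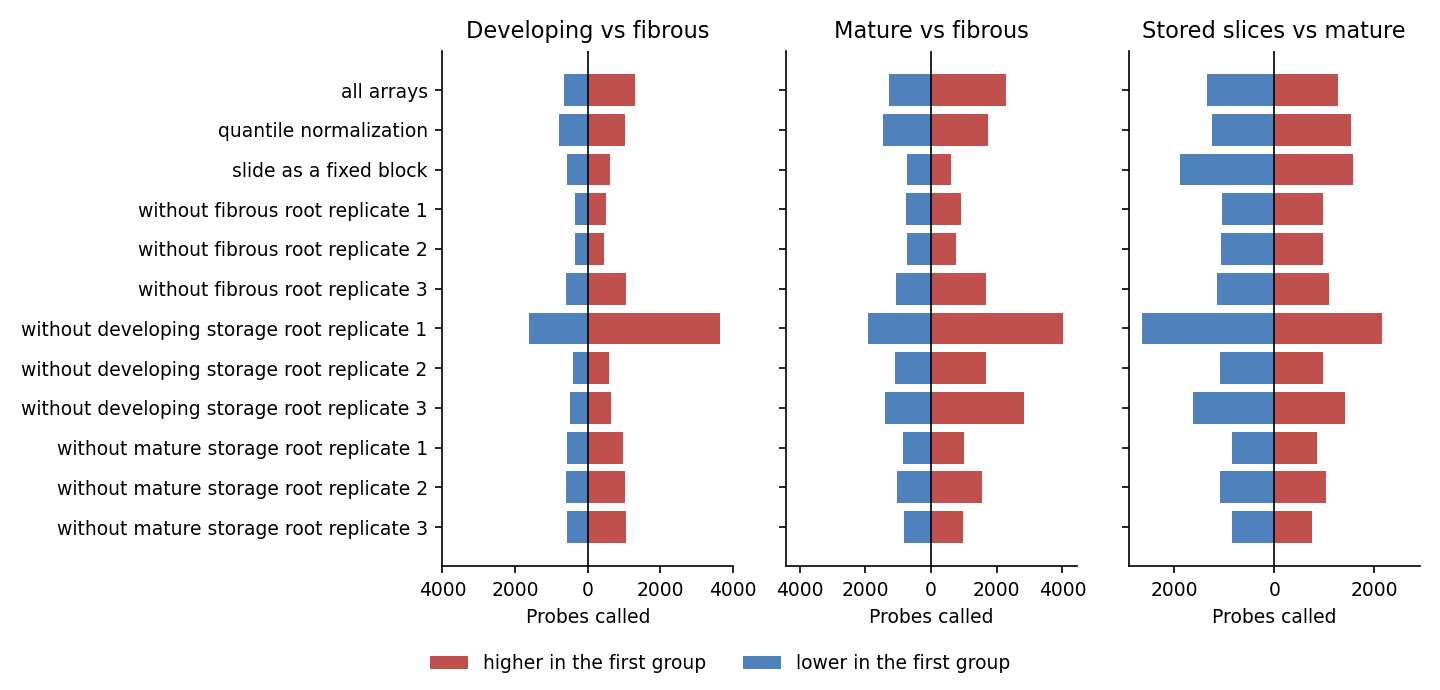
Probes with a limma adjusted p under 0.05 in 3 comparisons, drawn to the right where higher and to the left where lower in the first group, with all arrays, under quantile normalization, with slide as a block and without each stage array in turn, each panel with its own scale. Leaving out developing storage root 1 gave the highest counts among these settings in each panel, for example 5246 in developing against fibrous root. In the stored-slice panel the slide block sets the stored sample against mature storage root 3 alone, so that bar is no test.

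Probes called in both comparisons moved away from fibrous root in the same direction. A set of 1013 probes was higher and 621 probes were lower in both comparisons, and no probe was called in opposite directions. These are 78.6% of the higher and 95.5% of the lower calls of developing against fibrous root. Independent lists of these lengths would share 175 higher and 49.8 lower probes. The log2 changes correlated at r = 0.907 across probes, with a covariance of 1.30. In 20 simulations of unchanged groups against the same fibrous arrays these values averaged 0.498 and 0.11. The simulations held no slide effect and no pairing of replicate numbers, either of which could change these values. Part of the excess may come from the shared fibrous arrays, of which there are too few to split. A slide shift could also move both comparisons the same way, since all fibrous arrays lay on slide 1 and most storage root arrays on other slides. The agreement was not computed with slide as a block, so slide stays open here. Over all 3 stages 2559 probes differed (limma F test, adjusted p under 0.05), and in 1575 of them both storage root means lay above the fibrous mean, in 926 below. The F-test count was 1077 with slide as a fixed block. It was 1008 without fibrous root 1, 932 without fibrous root 2, 1699 without developing storage root 2, 1548 without mature storage root 1, 1628 without mature storage root 3 and 6073 without developing storage root 1.

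No probe differed between mature and developing storage roots at an adjusted p under 0.05 (limma, 16720 probes). At an unadjusted p under 0.05 there were 1286 probes, and the smallest adjusted p was 0.076. The median change was 0.02 log2 units. On simulated data, 200 probes set to differ 4-fold between these groups gave 126 recovered probes and 200 set to differ 8-fold gave 182. Of 200 set to differ 2-fold none was recovered. With so few probes changed, the adjusted threshold is stricter than where many change. In mature against fibrous root the simulation recovered no 2-fold change either, yet 3299 of the 3555 real calls were at least 2-fold and the rest were smaller. The simulation therefore shows low power for 2-fold changes in few probes, not that such changes could never be called. It also gave each probe the same spread in all groups. Pairs of real developing storage roots differed with an SD of up to 1.37, and pairs of mature roots with at most 0.69. The simulated recovery may thus overstate the power of this comparison. Without developing storage root 1, 137 probes differed, 82 higher and 55 lower in mature storage root, and no other left-out array gave more than 4. With slide as a fixed block 10 probes differed, and within slide 2, which held developing storage roots 2 and 3 and mature storage roots 1 and 2, none did. Both settings give the same changes, from the arrays of slide 2, with different estimates of the spread. They are therefore not separate checks.

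Stored slices of storage root differed from mature storage roots at 2617 of 17283 probes (limma, adjusted p under 0.05). The repeats were averaged and counted as 1 sample, which was assumed to vary like the stage samples. No spread between stored samples was measured, so these calls and p-values rest on the spread of the stage samples. Of the called probes, 1274 were higher and 1343 lower in the stored slices, with median changes of 2.28 and -2.62 log2 units. The split turned with the scaling, to 1536 higher and 1243 lower under quantile normalization and 1545 and 1243 in the authors' table. The median change over all tested probes was -0.15 with the 75th percentile scaling and 0.00 in both of these. At least 8-fold changes numbered 353 higher and 507 lower. The probe CUST_1059_PI390660497 (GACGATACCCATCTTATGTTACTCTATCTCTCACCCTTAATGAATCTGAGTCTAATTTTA) stood at 6.71 ± 0.13 (SD, n = 3) in mature storage root and at -5.56 and -4.22 in the repeats, 3096-fold lower (log2 change -11.60, SE 1.62, limma adjusted p = 0.0024). The probe CUST_20519_PI390660497 (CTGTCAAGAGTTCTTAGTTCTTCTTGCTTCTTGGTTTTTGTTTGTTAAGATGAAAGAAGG) was 624-fold lower (log2 change -9.29, SE 0.58, limma adjusted p = 0.00013). Its mean was 0.36 ± 0.86 (SD, n = 3) in fibrous, 2.79 ± 0.34 (SD, n = 3) in developing and 4.66 ± 0.16 (SD, n = 3) in mature storage root. The probe CUST_12493_PI390660497 (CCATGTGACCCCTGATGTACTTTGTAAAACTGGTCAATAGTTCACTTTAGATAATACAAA) was 152-fold higher in the stored slices (log2 change 7.25, SE 1.09, limma adjusted p = 0.0033). The probe CUST_11894_PI390660497 (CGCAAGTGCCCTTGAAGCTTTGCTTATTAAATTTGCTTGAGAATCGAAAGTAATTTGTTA) was 121-fold higher (log2 change 6.92, SE 1.63, limma adjusted p = 0.022), and without mature storage root 1 its adjusted p was 0.056, with a range of 0.0037 to 0.056 over its 21 alternatives. For CUST_12493_PI390660497 the mature mean was -3.68 ± 1.83 (SD, n = 3), and the log2 change was 8.30 without mature storage root 2. There were 506 probes well above background on both stored-slice arrays and on no mature array, and 225 on all mature arrays and no stored-slice array. Detection is read before scaling, and the 75th percentile was 3575 and 3717 on the stored-slice arrays against 1779 to 3006 on the mature ones. The count was 1706 without mature storage root 1, 1614 without mature storage root 3 and 4809 without developing storage root 1, which enters through the shared spread. With slide as a fixed block the change is that of the stored sample from mature storage root 3 alone, the only stage array of slide 3. Its median over the tested probes was -0.19 log2 units, and its count is not given. Within slide 3 a single mature array faces the stored slices, so no test is left there.

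**Figure D3:**
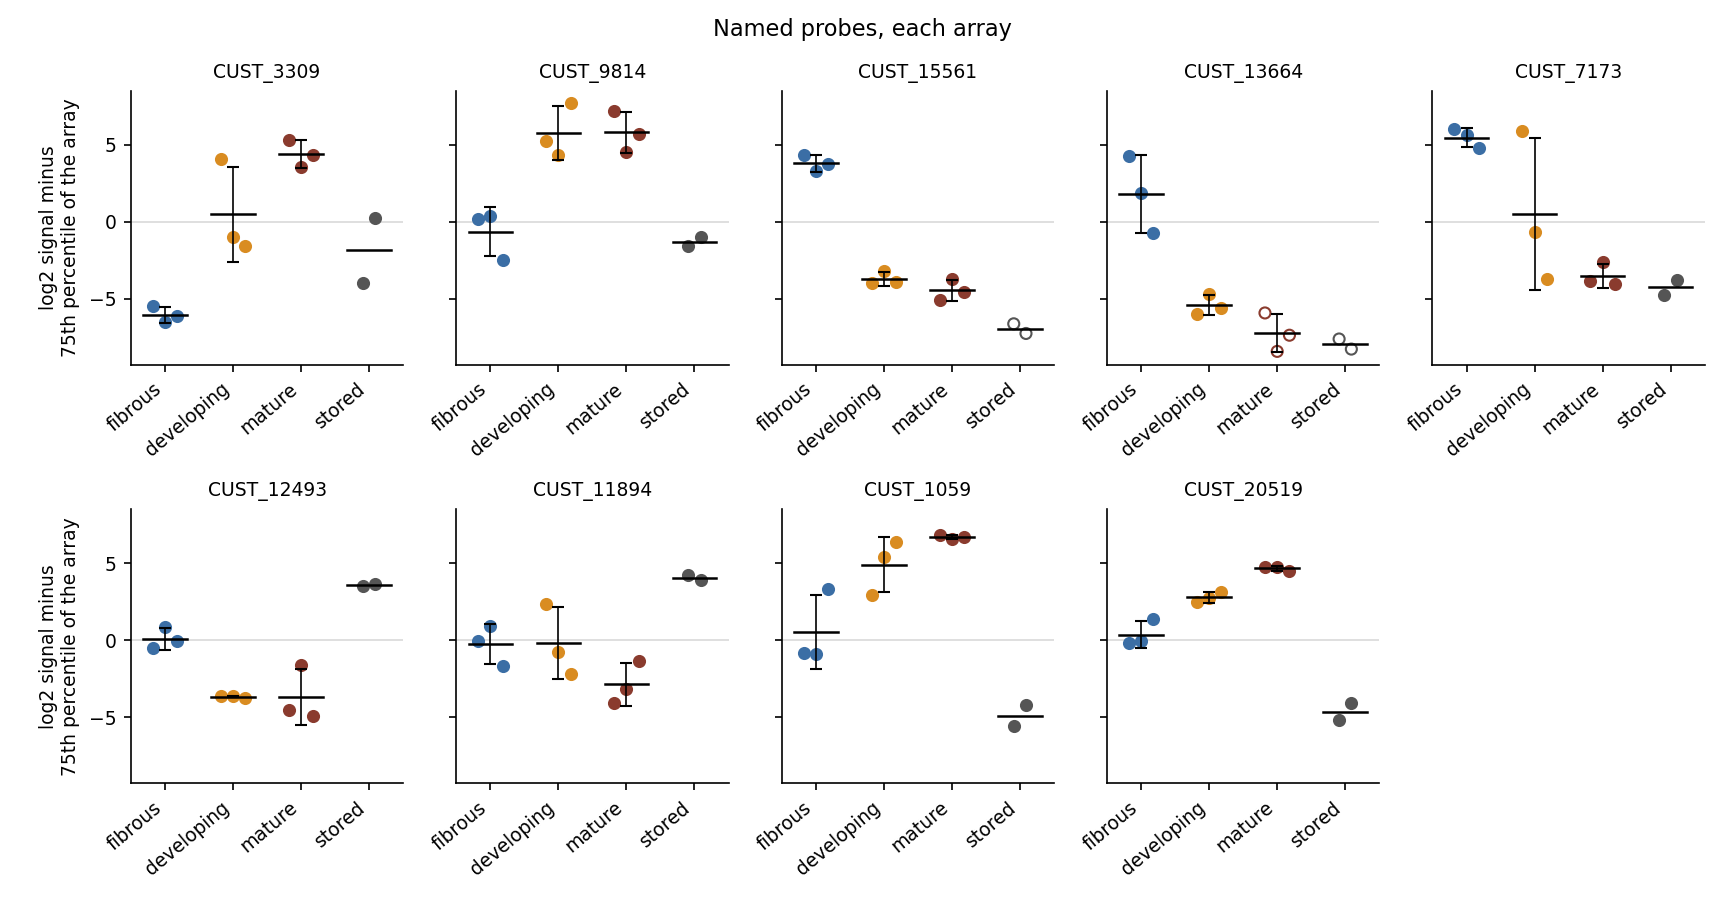
Log2 signal minus the array's 75th percentile for each named probe, 1 point per array, with group means as lines and SD as bars for the stage groups (n = 3 each). Open points are arrays where the probe was not well above background, and CUST_1059 stands at 6.71 in mature storage root and below -4 in both stored-slice arrays.

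The stored-slice arrays correlated with each other at r = 0.977 across 14072 probes. The SD of their log2 difference was 0.62, and 8.66% of the probes differed by over 2-fold after removal of the median difference. Pairs of fibrous roots had an SD of 0.55 to 0.65, pairs of mature roots 0.65 to 0.69, and pairs of developing storage roots 0.55 to 1.37. The repeats therefore differed by about as much as samples from different plants of the fibrous or mature stage. The labels do not say whether they came from the same slice, so this SD may hold a difference between slices as well as technical noise. Against mature roots the stored-slice arrays had an SD of 1.33 to 1.66.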

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

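The tests on developing storage root 1, the one on quantile normalization and the regroupings of the 3 stages that part the replicate numbers were chosen after the results were seen, and how the quantile test was to be read was made stricter after its value was seen. Groups of 3 arrays were too small for a test for outlying samples.

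Control probes lie outside the comparisons, and 6 of them were well above background on all spots of some stage array and on no spot of another. ETG10_236652 reached a median processed signal of 399.8 in developing storage root 3 and stood at 22.4 in fibrous root 3. DCP_1_0 reached 135 in developing storage root 2 and stood at 9.18 in fibrous root 2. DCP_22_4 reached 99.0, ETG10_195139 reached 80.6, and the control probes (+)eQC-41 and (+)eQC-42 reached 49.0 and 47.5. The negative control stood between 5.86 and 7.70 on the stage arrays.

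Developing storage root 1 differed from developing storage roots 2 and 3 more than any pair of fibrous or mature arrays differed. A shift between slides would carry its departure at full size (a slope of 1) into the difference of slide 1 fibrous from slide 2 mature arrays, and the highest of 6 slopes was 0.35, so slide as the whole cause is argued against, unless the stage change ran opposite to it. A fibrous root under this label is argued against, since the array's correlations with the fibrous arrays of the same slide (0.923 to 0.932) lay below the lowest r among those (0.975). Its highest correlation outside its group, 0.936 with a mature array, lay below the lowest r within the mature group (0.972). The mature arrays lie on other slides, so a slide effect could lower this r too. It therefore does not exclude a mature root under this label. A mixture of fibrous and mature tissue would lie between those, yet 438 probes were over 2-fold outside the range of all other stage arrays, against at most 141 for any other array (developing storage root 3). This argues against a mixture without a slide effect. With the mature arrays on other slides, a slide effect could carry a mixed sample outside that range. A smaller slide effect, a mature root under this label or a mixture, each with a slide effect, stay open as candidate explanations. So do a difference in the age or part of the root and a handling difference. Age, part of the root and handling were not tested.

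More probes were higher than lower in mature storage root than in fibrous root (64.0% of the calls), but not with slide as a fixed block (45.3%) or a random block (47.0%), and the share was near even without fibrous root 2 (50.5%) and at an adjusted p under 0.01 (50.1%). Dim probes lifted by the scaling are argued against as the whole cause, since 75.2% of the calls were higher among the brightest of 3 equal groups of probes, against 63.1% in the dimmest and 55.5% in between. The median change was largest in the dimmest group, 0.46 log2 units, against 0.34 in the brightest and 0.16 in between. A part from dim probes therefore stays open. Quantile normalization left 53.8% higher. It forces equal distributions on the arrays, and their shapes differed, with medians relative to the 75th percentile of -3.45 to -3.40 log2 units in fibrous and -3.36 to -3.22 in mature roots, so a scaling effect and a real shift in the balance of transcripts cannot be told apart, and slide stays open beside them.

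Regroupings of the arrays bear on the counts as follows. In developing against fibrous root the real split gave 1938 probes, and it was 1 of 10 splits to give as many, with 0 in the highest of the others. In mature against fibrous root the real split gave 3555 probes, and 1 of the 4 splits that part the replicate numbers gave as many, with 0 in the highest other. The remaining 6 splits, which keep same-numbered arrays together, gave 0 as well. In mature against developing storage root all 4 such splits gave 0, and the highest of the others gave 1. The splits are too few for a share under 0.05 in these comparisons. For the 3 stages, 36 splits part the replicate numbers, and only the real one (1 of 36) gave as many as 2559 probes. The highest other gave 2267. It kept the fibrous arrays together and mixed the storage roots, as did 2 others, and these 3 gave 1560 to 2267 probes. The 32 splits that part the fibrous arrays gave 0. Among 100 splits drawn from all 280, the real one included, 2 gave at least 2559, the other being 3235 with the fibrous arrays together. Fibrous and developing arrays were not read as paired, so both sets are given. Both shares are under 0.05, but they rank the real split as a whole, and the set of 36 was chosen after the results were seen. In that set the real split and the 3 others that kept the fibrous arrays together all gave 1560 probes or more. The shares therefore do not test the parting of fibrous from storage roots by itself, and chance is not excluded for it. Of the 96 drawn splits that part the fibrous arrays 93 gave no probe. The highest gave 1716, with fibrous roots 1 and 2 and developing storage root 1, all of slide 1, in a group. The slides also part the fibrous arrays from all storage roots but developing storage root 1, and with slide as a fixed block 1077 probes differed. Of these, 585 were also called without the block, and how much of the count belongs to slide is not settled by the splits.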

How the results depend on the processing

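The probes of reverse clone-end reads were left out only after the data were seen, and that left each count within 1.5 times. Slide as a fixed block gave 1187 probes for developing against fibrous root (1938 without it), 1359 for mature against fibrous root (3555), 10 for mature against developing storage root (0) and 1077 for the 3 stages (2559). Slide as a random block (estimated correlation 0.39) gave 1362 for mature against fibrous root and 1212 for the 3 stages. The fixed block estimates fibrous against storage root through developing storage root 1 alone by its construction. For the random block the cause was not tested. An adjusted p under 0.01 left 667, 1220, 905 and 793 probes for developing against fibrous, mature against fibrous, the 3 stages and the stored slices. Fitting only the compared groups gave 1201 and 5637 probes for developing and mature against fibrous root, the spread then coming from those arrays alone. For mature against developing storage root, normexp gave 2 probes and the variance trend with robust estimation 1, and the cause was not tested. Leaving out 1 array gave 783 to 5246 probes for developing against fibrous, 1478 to 5956 for mature against fibrous, 0 to 137 for mature against developing, 932 to 6073 for the 3 stages and 1614 to 4809 for the stored slices, each highest without developing storage root 1. The replicate block gave 2619 probes for developing against fibrous, 4547 for mature against fibrous, 0 for mature against developing and 3397 for the 3 stages. It moved none of these counts by over 1.5 times, shared 1885, 3484 and 2472 probes with the unblocked calls of developing against fibrous, mature against fibrous and the 3 stages, and ended no named probe's call. Of the fibrous and developing arrays not every one correlated best with its own number, for example fibrous root 3 at 0.42 with developing storage root 2 and 0.27 with its own.

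Left-out arrays aside, the settings that stayed within 1.5 times of the count were 11 of 14 for developing against fibrous, 9 of 13 for mature against fibrous, 11 of 14 for mature against developing, 8 of 11 for the 3 stages and 13 of 14 for the stored slices. For mature against developing the 2-fold minimum and the adjusted p under 0.01 could only leave the count of 0 as it was. For the stored slices the fixed block sets the stored sample against mature storage root 3 alone, so it is no check there. Quantile normalization and the authors' table hold nearly the same values, so they are not separate checks. The SD between the technical repeats ranged from 0.56 to 0.61 under normexp, quantile normalization and the authors' table (0.62). Each technical repeat alone gave 3512 and 2204 probes against the mature roots. The named probes kept their direction in all 247 alternatives and their side of the threshold in 241. They were chosen from these same data as the largest changes without overlap between the groups, so leaving out an array could not turn them. Several settings also leave the estimated change itself as it was. The tally is therefore no independent check of these probes. The gene lists were not run, having no annotation, and within slides there was no value for mature against fibrous root and no test for the stored slices. Signal over background limits the sizes of changes: in mature against fibrous root 105 of the 2274 higher probes were well above background on no fibrous array and 200 of the 1281 lower ones on no mature array. These numbers were 102 and 76 for developing against fibrous root and 158 and 193 for the stored slices against mature root.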

Other observations

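The tests of strand frames, GC content and probe overlaps in this part were set out before their values were seen. So was the test by brightness among the results flagged above. The rest of this part was chosen after the results were seen, as was the stricter reading of the frames test, which first counted in favour of the strand explanation.

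Probes that were higher in developing storage root than in fibrous root were, where called in both comparisons, more often lower than higher in the stored slices than in mature root. Of the 16720 probes tested in both comparisons, 241 were higher in the first and lower in the second, and 147 were lower in the first and higher in the second. In the same direction, 67 probes were higher in both and 84 lower in both. The means compared share no array, but both comparisons take their spread from the stage arrays, so the lists are not independent. Slide 2 held developing storage roots 2 and 3 and mature storage roots 1 and 2, and no fibrous or stored-slice array. A shift of slide 2 therefore enters these comparisons with opposite signs. With slide as a fixed block, developing against fibrous root had 1187 calls in place of 1938. The joint counts were not computed with that block, so slide stays open here. Independent lists would give 103 and 44.9 probes in the opposite directions, 88.9 higher in both and 52.2 lower in both, so the 84 lower in both exceed that value too and run against the opposite pattern. The log2 changes correlated at r = -0.24 (Spearman -0.31) across probes, which are not independent replicates. The probe CUST_9814_PI390660497 is of the first kind, with 5.74 ± 1.76 (SD, n = 3) in developing storage root and -1.60 and -1.01 in the stored slices.

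The stored-slice repeats differed from each other along the direction in which they differed from mature root. Of the 1274 probes higher in the stored slices, 78.1% were lower in repeat 2 than in repeat 1 (median difference -0.36 log2 units), and of the 1343 lower probes 67.1% were higher in repeat 2 (median 0.30). Over all 14072 probes the median difference was -0.09, so a small part of the first value is a general offset. The slope of that difference on the mean stored change was -0.14 over 14072 probes, and -0.15 with brightness in the model, which argues against a compressed signal on an array. An admixture of mature root RNA in repeat 2 was also tested: the lower probes gave a median admixed share of 2.66% (10th to 90th percentile -8.18 to 18.2%), which would change the higher probes by -0.04 log2 units, against the measured -0.36. The same slope for pairs of arrays of a stage ran from -0.20 to 0.07. The probe CUST_3309_PI390660497 differed most visibly among the named ones, at -3.96 in repeat 1 and 0.22 in repeat 2.

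Probes whose source names mark the reverse reads of clone ends were seldom well above background: 37.1% of 3147 were detected on all 9 stage arrays, against 70.4% of 2914 probes from forward reads, and in 1928 clones with a probe at each end 796 had only the forward and 112 only the reverse probe detected (exact two-sided McNemar p = 8.7e-128). GC content is argued against as the cause, since the gap of 33.3 percentage points was still 32.0 within strata of GC content. A candidate explanation is that the reverse probes lie on the strand opposite to the transcript. All 5 overlaps of at least 30 bases between a reverse-read probe and any other probe were in opposite orientation (100%), against 12 of 108 between other probes (Fisher's exact test, two-sided p = 4.4e-05). The other probes include those of forward reads, and the partners in these 5 overlaps were not told apart by source. Reading frames did not settle it, since forward-read probes had 0.23 more stop-free frames on their own than on the other strand and reverse-read probes -0.01, a difference of 0.24 (SE 0.03) that gives no strand for the reverse ones. Among the reverse-read probes called between mature and fibrous root, 263 were higher and 30 lower, against 286 and 187 among forward-read probes, and no biological explanation was tested.

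Overlapping probes in the same orientation gave like values. Over 96 such pairs the mean log2 levels correlated at 0.975, and over 85 tested pairs the change between mature and fibrous root at 0.993. For 17 pairs in opposite orientation the levels correlated at -0.50, with a median difference of 5.45 log2 units.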
